A study of Oryza sativa with 16 samples.

How the data were processed

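Shoots and roots of 15-day-old hydroponic rice seedlings were sampled after 24 h without treatment or with arsenic, thiourea or both, and the samples form 8 groups of 2 arrays. The labels give no doses. Per the labels' protocols, total RNA was labelled with Cy3 by Quick-Amp labelling and hybridised to a custom whole-genome rice array. Deposited scanner files hold signal intensity values for each probe, made with Agilent Feature Extraction 11.5.1.1, per the file headers. Its processed signal is background-subtracted and not scaled between arrays. Per the file headers, the same files flag spots well above background, saturated spots and spots with non-uniform signal. The deposited value table holds log2 processed signal minus the array's 75th percentile, as found by recomputing it: it matched within 0.001 log2, with a largest constant difference of 0.000992. Its column medians lie between -3.30 and -2.59.

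The arrays hold 59293 probes beside 1319 control spots. Genes were taken from rice gene identifiers in the array's own description for 53078 probes and from the probe name for 6093, and 122 probes were kept under an accession only. None of the 1043 probes with RefSeq accessions matched the reference table (0 matched), so gene names are those of the array's descriptions. On an array, 53.3% to 67.0% of probes were well above background, 0 were saturated, and 10 to 262 spots were non-uniform. The 1393 non-uniform spots were left out. The number of arrays limits the precision.

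Processed signal was taken to log2 and scaled to the array's 75th percentile over all non-control probes. Of the 8791 identifiers with more than 1 probe, the probe with the highest mean over the 16 arrays was kept. A gene was tested in a tissue if it was well above background on both arrays of at least 1 group of that tissue, and in both tissues for the difference between them. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with pooled variance (8 residual and 3.12 prior degrees of freedom) and Benjamini-Hochberg adjustment over the genes of each comparison; adjusted p under 0.05 was a call. In each tissue As, TU and As+TU were compared with control, As+TU with As and with TU, and the interaction of As and TU was tested. For 3 of these (As against control, TU against control, As+TU against As) the root change minus the shoot change was tested. Groups of 2 are too small for a permutation test or for other splits of the samples.

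Genes are named by this rule. For As, TU and As+TU against control and for As+TU against As in each tissue, the 6 largest fitted rises and 6 largest fitted falls among called genes with a described function, whose groups' arrays did not overlap, are named; the order is not measured where a gene has only a bound. The interaction and the organ differences name 3 in each direction. Any member of a gene list may be named, and comparisons without calls name list members only. Genes outside the rule are said to be so where they appear. The comparisons, the rule and the gene lists, apart from those mentioned below, were set before the data were examined.

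The 35 gene lists were matched by words of the descriptions and by locus. Each with at least 3 measured genes was tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, and adjusted over the lists of a comparison. Shifts are medians minus the median of all genes. Tests and shifts leave out genes with a non-uniform spot on any array, while counts of higher and lower genes cover all genes measured. Over the 158 called lists, 55 of which lost no gene, the shift over all measured genes differed by at most 0.86, in the root-enriched list, with a median difference of 0.004 and 0 changes of sign. In 106 called lists of comparisons between 2 groups, setting genes near background to their bound moved the shift by at most 0.73 and changed 0 signs. The list of ABC and MATE transporters was corrected after the list tests had been seen, to remove heavy-metal proteins that matched one of its words. It is called in 5 comparisons as corrected. As first matched, with 153 genes, it is called in none of those 5, and it is called for TU against control in shoots, which the corrected list is not (shift 0.05, adjusted p = 0.0286). Words of other lists were corrected before any list test was run. A list of low-oxygen genes was compiled after gene values had been seen.

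All shoot arrays lay on one slide and all root arrays on the other, so slide and tissue cannot be told apart in signal levels, while an additive slide effect cancels in changes within a tissue. Within a slide, control and As lay in row 1, and As+TU and TU in row 2, so row cannot be told apart from thiourea; As against control and As+TU against TU each lie within a row. The headers show 2 scan sessions. As+TU array 1 of shoots, and control array 1 and TU array 2 of roots, were read in the later one, and the other 13 arrays in the earlier one. Each comparison was repeated with scan session as a block within tissue and without the later-scanned arrays.

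Shared-control correlations were compared with 5 simulated data sets of unchanged groups and, as chosen after the data had been seen, with fits that gave each comparison 1 control array of its own. On simulated data with 200 changed genes, the model called 0% of 2-fold, 19.4% of 4-fold and 54.5% of 8-fold changes for As against control in shoots (26724 genes), with 0 false calls of 49. In roots (25635 genes) it called 0%, 26.9% and 65.2%, with 7 false calls of 68. For the interaction it called 0% at each size in shoots, and 0%, 1.49% and 7.58% in roots.

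The alternatives were quantile normalization, scaling to the median of genes above background on all arrays, normexp background correction (offset 50), no filter and a strict filter on dim probes, every probe separately, the value table, array weights, an intensity trend with robust variance, only the tissue's own arrays, a replicate block, at least a 2-fold change, and leaving out each array in turn, where a lone array is assumed to vary like the other groups.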

Results

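Transcript levels were measured on 16 one-colour arrays, each hybridised with labelled total RNA from the shoots or roots of 15-day-old hydroponic rice seedlings after 24 h of treatment. The 8 groups were shoots and roots of untreated seedlings (control) and of seedlings given arsenic (As), thiourea (TU, a sulfur compound that scavenges oxidants) or both (As+TU) through the medium, with 2 arrays in each group. Each array carried 59293 probes for 42609 gene identifiers. Between 53.3% and 67.0% of probes were well above background on an array, and the 75th percentile of signal lay between 178.7 and 416.5 intensity units. Replicate arrays correlated across genes at r = 0.936 to 0.973 in shoots and 0.938 to 0.959 in roots; genes are not independent replicates. The labels do not state whether replicates were grown separately, so the p-values measure the spread between these samples. Fold changes below are on the log2 scale with their standard error and n = 2 arrays per group, and adjusted p-values come from limma. A gene that was not well above background on either array of its lower group has only a bound, computed against the higher of its own signal and the array's background limit there and written as at least N-fold.

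The effect of arsenic on shoots was compared first, since it is the reference for any action of thiourea. Dehydrin and late embryogenesis abundant (LEA) genes, whose proteins protect drying cells, were among the large rises. The dehydrin RAB 16D (Os11g0453900) was at least 3160-fold higher (adjusted p = 7.26e-06), with a normalised log2 signal of 7.49 ± 0.16 (SD, n = 2) on the arsenic arrays. A DHN1-like dehydrin (Os11g0451700) was at least 2390-fold higher (adjusted p = 8.33e-05), a plasma membrane protein induced by abscisic acid (Os05g0381400, PM19-like) at least 1840-fold, and an LEA repeat protein (Os01g0705200) at least 1380-fold. A TspO-related protein (Os05g0151200) was at least 439-fold higher and a group 1 LEA protein (Os06g0324400) at least 352-fold. The LEA-like gene Os05g0542500, which was detected in controls, rose by 10.32 ± 0.43 (adjusted p = 1.63e-06), and the protein phosphatase 2C gene Os06g0698300, of a family that restrains abscisic acid signalling, by 7.27 ± 0.58 (adjusted p = 4.41e-05).

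Expansin genes, which loosen growing cell walls, were among the large falls in arsenic-treated shoots. A beta-expansin (Os10g0555900) changed by -6.44 ± 0.51 (adjusted p = 4.41e-05) and the alpha-expansin OsEXPA2 (Os01g0823100) by -5.98 ± 0.43 (adjusted p = 2.68e-05), while OsEXPA4 (Os05g0477600) was at least 44.0-fold lower. The cytochrome P450 genes Os09g0275400 and Os10g0144700 were at least 76.9-fold and 35.8-fold lower, a homeodomain-like protein (Os05g0579600) changed by -6.06 ± 0.53, and a SAM-dependent carboxyl methyltransferase (Os02g0719600) was at least 26.2-fold lower. The A-type response regulators 2 (Os02g0557800) and 4 (Os01g0952500), which are induced by cytokinin and dampen its signal, changed by -3.92 ± 0.35 and -2.30 ± 0.36. Among metal-binding and stress genes, the type 1 metallothionein Os12g0571000 rose by 7.21 ± 0.62 (adjusted p = 6.62e-05), a second metallothionein (Os03g0288000) by 5.30 ± 0.45, heat shock protein 70 (Os03g0277300) by 6.34 ± 0.48 and alternative oxidase 1a (Os04g0600200), which diverts electrons in mitochondria, by 2.35 ± 0.39.

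In all, limma called 3145 of 26721 genes in arsenic-treated shoots, 1421 higher and 1724 lower, against 7219 at an unadjusted p under 0.05; 584 of the calls have only a bound. The median change of all genes was -0.29, and group shifts are given relative to that median. The higher share was 45.2% and became 54.1% with quantile normalization and 36.6% with normexp background correction, which put the median of all genes at -0.12 and -0.35. All 4 arrays compared were read in the earlier scan session. The count was 2849 with scan session as a block and 2990 without the later-scanned arrays. Leaving out control array 1 gave 1444 calls, control array 2 1250, arsenic array 1 1568 and arsenic array 2 1670.

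Among the gene lists, the 79 measured abscisic acid, LEA and dehydrin genes shifted up by 0.76 in arsenic-treated shoots (camera adjusted p = 7.4e-10, and 0.133 with an estimated correlation). Of them 22 were higher and 4 lower, or 31 and 4 adjusted over the list alone. The 109 heat shock genes shifted up by 0.58, with 18 higher and 2 lower, or 21 and 4 over the list alone (adjusted p = 1.63e-04, and 0.0954 with an estimated correlation). Cell wall expansion genes shifted by -0.91, with 3 higher and 15 lower of 52, or 4 and 17 over the list alone (adjusted p = 0.00468, and 0.563 with an estimated correlation). Without control array 2 the shift was -0.588. Calcium signalling genes shifted up by 0.50 with 18 higher and 4 lower of 162, or 21 and 5 over the list alone (adjusted p = 0.0145, and 0.388 with an estimated correlation). The list was not called without control array 2 (0.377, adjusted p = 0.0532) or arsenic array 1 (0.275, adjusted p = 0.0797). The 139 cytosolic ribosomal protein genes lay 0.53 above the median of all genes with 4 higher and 0 lower, or 0 and 0 over the list alone (adjusted p = 4.29e-05, and 0.675 with an estimated correlation). None of the 158 list calls made over the 15 comparisons held with an estimated correlation, and 62 held in each fit that left out 1 array. Sulfate assimilation genes, with 0 higher and 6 lower of 22, were not called as a group (adjusted p = 0.0701), nor were the photosynthesis genes, with 2 higher and 3 lower of 59 (adjusted p = 0.0994).

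Roots, which were in contact with the medium, gave the second arsenic comparison. The silicon channel Lsi1 (Os02g0745100), which also carries arsenite into roots, changed by -5.67 ± 0.42 (adjusted p = 1.26e-05), and the silicon efflux transporter Lsi2 (Os03g0107300), which passes arsenite on towards the xylem, by -6.09 ± 0.64 (adjusted p = 1.04e-04). Of 23 sulfate assimilation genes 10 were higher and 3 lower, and APS reductase (Os07g0509800) rose by 5.16 ± 0.34 (adjusted p = 6.68e-06), a cysteine synthase (Os12g0625000) by 3.70 ± 0.36 (adjusted p = 6.91e-05) and an ATP sulfurylase (Os03g0743900) by 2.65 ± 0.28 (adjusted p = 1.02e-04). The tau class glutathione S-transferase Os10g0527400, of a family that attaches glutathione to toxic compounds, rose by 10.07 ± 0.79 (adjusted p = 1.86e-05) from a level above background on 1 of 2 control arrays. Glutathione synthase Os12g0263000 changed by -5.54 ± 0.61, and the glutaredoxin Os02g0618100 rose by 5.63 ± 0.42. A high-affinity nitrate transport component (Os02g0595900) changed by -5.08 ± 0.48 (adjusted p = 5.75e-05), and the ammonium transporter Amt1;2 (Os02g0620500) was at least 38.2-fold lower.

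Large rises in arsenic-treated roots included an alpha-amylase 3D gene (Os08g0473900), which breaks down starch, at least 1630-fold higher (adjusted p = 8.25e-06), and a gibberellin-regulated protein (Os05g0432200), at least 1010-fold. A glycine-rich RNA-binding protein (Os05g0223200) was at least 785-fold higher and an AP2 factor similar to RAP2.2 (Os02g0546600) at least 615-fold. The germin-like oxalate oxidase Os03g0694000 rose by 11.74 ± 0.59, with control signal above background on 1 array, and the small heat shock protein Oshsp18.0 (Os03g0267000) by 10.55 ± 0.37 (adjusted p = 2.63e-07). Heat shock protein 70 (Os03g0277300) rose by 8.23 ± 0.48, alternative oxidase 1b (Os04g0600300) by 5.93 ± 0.63 and a glucosyltransferase (Os02g0755900) by 8.10 ± 0.51. On the lower side, each as a bound, a salt stress-induced protein (Os01g0355250) was at least 279-fold lower and a BCH2-like protein (Os02g0112100) 146-fold. A gene similar to the defence gene PBZ1 (Os12g0555100) was at least 91.1-fold lower, a GDSL lipase (Os01g0216000) 85.8-fold and an aspartic peptidase (Os10g0537800) 23.6-fold. A cupredoxin (Os11g0428800) changed by -6.77 ± 0.55 and the peroxidase Os05g0135500 by -4.28 ± 0.27.

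**Figure D1:**
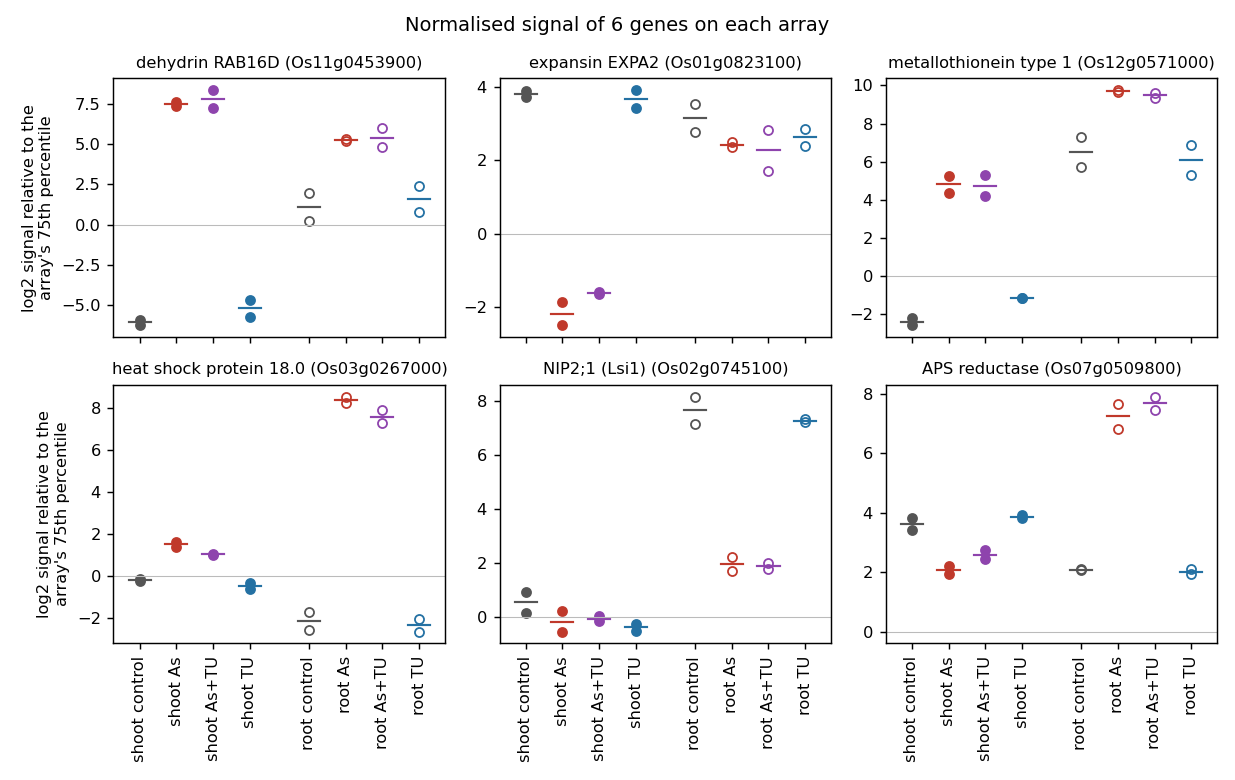
Log2 signal relative to the array's 75th percentile for 6 genes on all 16 arrays, with points for arrays, bars for group means, filled symbols for shoots and open symbols for roots. Lsi1 (Os02g0745100) averaged 7.64 on root control arrays and 1.97 on root arsenic arrays, and Oshsp18.0 (Os03g0267000) averaged -2.15 and 8.40.

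Across arsenic-treated roots limma called 4210 of 25635 genes, 2404 higher and 1806 lower, against 7574 at an unadjusted p under 0.05; 847 have only a bound. The count was 2693 with scan session as a block and 2234 without the later-scanned arrays; the later session held control array 1 and no arsenic array of roots, so no comparison could be made within it. Leaving out control array 1 gave 2229 calls and arsenic array 1 gave 2156. The median change of all genes was -0.05, or -0.14 with quantile normalization.

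Glutathione S-transferase genes shifted up by 1.33 in arsenic-treated roots, or 1.34 with scan session as a block and 1.11 without the later-scanned arrays (adjusted p = 2.76e-05, and 0.43 with an estimated correlation). Of 61, 25 were higher and 5 lower, or 33 and 11 over the list alone. Heat shock genes shifted up by 0.42, or 0.52 with the block and 0.64 without the later-scanned arrays, with 29 higher and 4 lower of 111, or 35 and 5 over the list alone (adjusted p = 5.01e-05, and 0.08 with an estimated correlation). The shift was 0.637 without control array 1 and 0.688 without arsenic array 2. Abscisic acid, LEA and dehydrin genes shifted up by 0.75 (block 0.877, earlier-scanned arrays 0.69), close to the 0.76 of shoots, with 27 higher and 7 lower of 82, or 29 and 9 over the list alone (adjusted p = 5.01e-05, and 0.279 with an estimated correlation). Sulfate assimilation genes shifted up by 0.92 (block 0.995, earlier-scanned arrays 1.03), with 10 higher and 3 lower of 23, or 11 and 4 over the list alone (adjusted p = 0.0237, and 0.323 with an estimated correlation). Without control array 2 the shift was 0.508. The 5 root-enriched genes, which include Lsi1, Lsi2 and the root-specific RCc2, had 0 higher and 4 lower, also over the list alone. Their shift was -4.75 over the 4 genes free of non-uniform spots that entered the test and -3.89 over all 5 (block -4.79, earlier-scanned arrays -5.02 over the 4; adjusted p = 0.00153, and 0.279 with an estimated correlation). UDP-glycosyltransferase genes, which attach sugars to small molecules, shifted up by 0.50 (block 0.45, earlier-scanned arrays 0.44), with 26 higher and 8 lower of 97, or 30 and 12 over the list alone (adjusted p = 0.00161, and 0.593 with an estimated correlation). Without control array 2 the shift was 0.809. Nitrogen uptake and assimilation genes shifted by -0.62, with 4 higher and 9 lower of 35, or 5 and 10 over the list alone (adjusted p = 0.0252, and 0.43 with an estimated correlation). With the block their shift was -0.44 and no longer called (adjusted p = 0.0541), and it was -0.90 in the earlier-scanned arrays. They were not called without control array 2 (-0.512, adjusted p = 0.0813) or arsenic array 1 (-0.376, adjusted p = 0.0833). The arsenic-handling genes, with 2 higher and 4 lower of 16, or 2 and 6 over the list alone, were not called as a group (adjusted p = 0.0826).

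Photosynthesis genes lay 0.54 above the median of all genes in arsenic-treated roots (adjusted p = 0.0263, and 0.815 with an estimated correlation), with 5 higher and 0 lower of 51, or 3 and 0 over the list alone. The shift was not called with scan session as a block (0.15, adjusted p = 0.296) or in the earlier-scanned arrays (0.14, adjusted p = 0.373). The median signal of the 59 photosynthesis genes was -1.21 on root arsenic array 1 and 2.89 on array 2, a gap larger than that between the root control arrays, at -0.78 and 0.77. The direction rested on arsenic array 2. Without it the list was called lower, with a shift of -1.4 (adjusted p = 0.00114), and without arsenic array 1 the shift was 2.84. It was 1.44 without control array 2 and 0.143, not called, without control array 1 (adjusted p = 0.368).

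**Figure D2:**
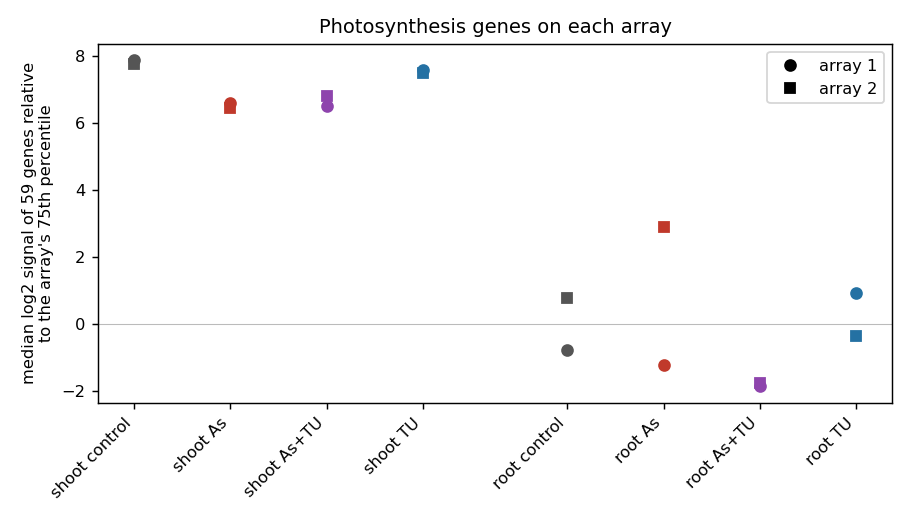
Median log2 signal of 59 photosynthesis genes on each array, relative to the array's 75th percentile, with circles for array 1 and squares for array 2 of a group. Shoot arrays lie between 6.46 and 7.88, and root arrays between -1.85 and 2.89, with root arsenic array 2 the highest root array.

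Whether arsenic acted differently in the 2 organs was tested as the root change minus the shoot change. Oshsp18.0 (Os03g0267000) rose more in roots by 8.82 ± 0.53 (adjusted p = 3.5e-05), and the glutathione S-transferase Os10g0530500, called higher in roots and lower in shoots and above background on 1 of 2 root control arrays, differed by 7.76 ± 0.46 (adjusted p = 3.5e-05). APS reductase (Os07g0509800) differed by 6.71 ± 0.48 (adjusted p = 6.45e-05) and the cysteine synthase Os12g0625000 by 5.03 ± 0.52 (adjusted p = 4.28e-04). Lsi1 (Os02g0745100) differed by -4.96 ± 0.59 and OsEXPA2 (Os01g0823100) by 5.25 ± 0.61. A thaumatin-like defence protein (Os03g0663400) differed by -5.76 ± 0.66 and the drought-related NAC factor Os11g0126900 by -4.37 ± 0.50, both with the larger change in shoots.

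The rule for naming gave the 3 largest fitted differences in each direction among described genes. Of these 6 genes 4 were not above background on any array of at least 1 group compared, so the size of their difference is not measured. The alpha-amylase 3D gene (Os08g0473900, adjusted p = 1.04e-04), Os05g0223200 (adjusted p = 1.29e-04) and the B12D family gene Os07g0604600 (adjusted p = 8.29e-04) had the higher change in roots and were above background on 0 of 2 root control arrays. The dehydrin RAB 16D (Os11g0453900, adjusted p = 4.99e-04) had the higher change in shoots and was above background on 0 of 2 shoot control arrays. An aldehyde oxidase (Os07g0281800), which was above background on 1 shoot control array and 1 root arsenic array, differed by -7.50 ± 0.96. The urea transporter-like gene Os10g0580400 differed by -8.14 ± 1.17 (adjusted p = 0.00222) and was above background on both arrays of all 4 groups.

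In this comparison limma called 1730 of 22665 genes, 1091 with the higher change in roots and 639 in shoots, against 5775 at an unadjusted p under 0.05. With quantile normalization the calls were 2065, 1018 and 1047 by direction, so the higher share went from 63.1% to 49.3%. Scan session as a block gave 935 calls and omission of the later-scanned arrays 741. Leaving out shoot control array 1 gave 1035, shoot control array 2 712, shoot arsenic array 1 829, shoot arsenic array 2 1032 and root control array 1 832. Across genes the arsenic changes of shoots and roots correlated at r = 0.286, with 498 genes higher in both where independent lists would share 119, 316 lower in both against 88.4, and 114 in opposite directions.

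Sulfate assimilation genes differed between the organs by 1.69 (block 1.94, earlier-scanned arrays 1.92), with 7 of 21 higher in roots and 0 lower, or 10 and 0 over the list alone (adjusted p = 3.66e-04, and 0.277 with an estimated correlation). Glutathione S-transferase genes differed by 1.03 (block 0.73, earlier-scanned arrays 0.57), with 14 higher and 1 lower of 48, or 18 and 1 over the list alone (adjusted p = 4.17e-04, and 0.787 with an estimated correlation). Without root control array 1 the shift was 0.568. UDP-glycosyltransferase genes differed by 0.84 (block 0.77, earlier-scanned arrays 0.71), with 23 higher and 0 lower of 88, or 26 and 2 over the list alone (adjusted p = 7.04e-04, and 0.787 with an estimated correlation). Calcium signalling genes differed by -0.61 (block -0.54, earlier-scanned arrays -0.47), with 3 higher and 11 lower of 157, also over the list alone (adjusted p = 0.0105, and 0.787 with an estimated correlation). They were not called without root arsenic array 2 (-0.524, adjusted p = 0.0687). Abscisic acid, LEA and dehydrin genes did not differ as a group by camera (-0.52, adjusted p = 0.127), but did with quantile normalization (-0.563, adjusted p = 0.0313). Photosynthesis genes differed by 1.62 (block 1.18, earlier-scanned arrays 1.1, quantile normalization 0.951), with 1 higher and 0 lower of 51, or 0 and 0 over the list alone (adjusted p = 0.00169, and 0.81 with an estimated correlation). The direction rested on root arsenic array 2. Without it the difference was -0.421 and not called (adjusted p = 0.645), and without root arsenic array 1 it was 3.68.

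Arsenic given together with thiourea was set against untreated seedlings to see which arsenic responses were present in the combined treatment. In shoots RAB 16D (Os11g0453900) was at least 3920-fold higher (adjusted p = 6.59e-06), the DHN1-like dehydrin (Os11g0451700) at least 2750-fold, the PM19-like gene (Os05g0381400) at least 2020-fold, the LEA repeat protein (Os01g0705200) at least 1050-fold and the TspO-related gene (Os05g0151200) at least 456-fold. Os05g0542500 rose by 10.54 ± 0.43 (adjusted p = 1.29e-06), the metallothionein Os12g0571000 by 7.14 ± 0.62 and alternative oxidase 1a (Os04g0600200) by 2.71 ± 0.39. A methyl chloride transferase (Os03g0843800) changed by -6.21 ± 0.89 (adjusted p = 0.00126), the homeodomain-like gene Os05g0579600 by -5.83 ± 0.53, the beta-expansin Os10g0555900 by -5.44 ± 0.51 and OsEXPA2 (Os01g0823100) by -5.42 ± 0.43. The P450 genes Os09g0275400 and Os10g0144700 were at least 53.0-fold and 24.7-fold lower, and a disease resistance-responsive gene (Os07g0637700) at least 10.1-fold lower.

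The combined treatment called 9142 of 26718 shoot genes, 2758 higher and 6384 lower, against 12601 at an unadjusted p under 0.05, and 2720 of the calls have only a bound. The median of all genes was -0.44, or -0.24 with quantile normalization and -0.35 with normexp background correction. Quantile normalization split its 8511 calls into 3418 higher and 5093 lower, a higher share of 40.2% where the percentile scaling gave 30.2%. As+TU array 1 was read in the later scan session, alone among shoot arrays, so no comparison within that session was possible. With scan session as a block the count was 3487, and without the later-scanned arrays it was 3766. Leaving out control array 1 gave 4015, control array 2 2133 and As+TU array 1 4105. The split also depended on these arrays: the higher share was 44.1% with the block (1538 higher, 1949 lower), 45% without As+TU array 1 (1847 and 2258), 45.4% without control array 2 (968 and 1165) and 19.1% without As+TU array 2 (1436 and 6099).

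Abscisic acid, LEA and dehydrin genes shifted up by 1.13 in As+TU shoots, or 1.21 with scan session as a block and in the earlier-scanned arrays, with 31 higher and 4 lower of 79, or 32 and 4 over the list alone (adjusted p = 3.09e-10, and 0.13 with an estimated correlation). Glutathione S-transferase genes shifted up by 0.81 (1.17 with the block), with 19 higher and 7 lower of 50, or 20 and 10 over the list alone (adjusted p = 0.00857, and 0.605 with an estimated correlation). Cell wall expansion genes shifted by -1.74, or -1.01 with genes near background at their bound and -1.08 both with the block and without As+TU array 1, with 4 higher and 26 lower of 52, or 5 and 32 over the list alone (adjusted p = 0.00858, and 0.596 with an estimated correlation). The 7 alternative respiration genes, which had 2 higher and 0 lower, also over the list alone, shifted up by 1.37 (1.47 with the block; adjusted p = 0.0117, and 0.187 with an estimated correlation).

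In roots given both compounds, Lsi1 (Os02g0745100) changed by -5.74 ± 0.42 (adjusted p = 1.59e-05), Lsi2 (Os03g0107300) by -5.95 ± 0.64 and the NOD26-like membrane protein Os06g0228200 by -3.71 ± 0.58 (adjusted p = 0.00156). APS reductase (Os07g0509800) rose by 5.59 ± 0.34, ATP sulfurylase (Os03g0743900) by 2.62 ± 0.28 and the cysteine synthase Os12g0625000 by 3.15 ± 0.36. Oshsp18.0 (Os03g0267000) rose by 9.74 ± 0.37 (adjusted p = 6.27e-07), the oxalate oxidase Os03g0694000 by 10.84 ± 0.59 and an ethylene-responsive coactivator (Os06g0592500) by 9.92 ± 0.57. The bounds were at least 1020-fold higher for alpha-amylase 3D (Os08g0473900), 551-fold for Os02g0546600, 448-fold for Os05g0432200 and 364-fold for Os05g0223200. On the lower side they were at least 237-fold for Os01g0355250, 98.4-fold for the urea transporter-like Os10g0580400, 76.5-fold for PBZ1 (Os12g0555100), 72.0-fold for Os01g0216000 and 58.0-fold for a glyoxalase family gene (Os01g0173600). The BCH2-like gene Os02g0112100 changed by -7.89 ± 1.37 and the nitrate transport component Os02g0595900 by -5.75 ± 0.48. Nicotianamine synthase 1 (Os03g0307300), which makes a metal chelator, was at least 75.9-fold lower.

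That comparison called 3414 of 25634 genes, 1892 higher and 1522 lower, against 6842 at an unadjusted p under 0.05; 760 have only a bound. The count was 2218 with scan session as a block and 2242 without the later-scanned arrays. Leaving out control array 1 gave 2235, control array 2 1829, As+TU array 1 2250 and As+TU array 2 1863.

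The 5 root-enriched genes had 0 higher and 4 lower in As+TU roots, also over the list alone. Their shift was -4.84 over the 4 genes tested and -4.04 over all 5 (block -4.91, earlier-scanned arrays -5.12 over the 4; adjusted p = 2.1e-04, and 0.141 with an estimated correlation). Photosynthesis genes shifted by -2.34 (block -3.02, earlier-scanned arrays -3.09), with 2 higher and 2 lower of 51, or 1 and 1 over the list alone (adjusted p = 1.95e-04, and 0.6 with an estimated correlation). Without control array 2 their shift was -1.37.

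Class III peroxidase genes, whose products act in the cell wall, shifted by -1.11 in As+TU roots (block -1.08, earlier-scanned arrays -0.92), with 5 higher and 25 lower of 105, or 6 and 33 over the list alone (adjusted p = 1.13e-04, and 0.326 with an estimated correlation). Heat shock genes shifted up by 0.50 (block 0.55, earlier-scanned arrays 0.68), with 23 higher and 3 lower, or 28 and 4 over the list alone (adjusted p = 3.42e-05, and 0.0555 with an estimated correlation). Abscisic acid, LEA and dehydrin genes shifted up by 0.49 (block 0.524, earlier-scanned arrays 0.488), with 24 higher and 8 lower, or 27 and 9 over the list alone (adjusted p = 5.42e-04, and 0.274 with an estimated correlation). Sulfate assimilation genes shifted up by 0.55 (block 0.59, earlier-scanned arrays 0.60), with 7 higher and 1 lower, or 10 and 3 over the list alone (adjusted p = 0.0193, and 0.274 with an estimated correlation). The shift was 1.0 without As+TU array 2 and not called without As+TU array 1 (0.765, adjusted p = 0.0545). Nitrogen uptake genes shifted by -0.88 (block -0.93, earlier-scanned arrays -1.08), with 5 higher and 9 lower, or 7 and 12 over the list alone (adjusted p = 0.00172, and 0.274 with an estimated correlation). Without control array 2 the shift was -0.56. Genes for ABC and MATE transporters, which export compounds, shifted up by 0.44 with 13 higher and 1 lower of 66, or 14 and 1 over the list alone (adjusted p = 0.00656, and 0.0978 with an estimated correlation). The shift was 0.66 without control array 1 and 0.17 without As+TU array 2. This list had been corrected after its test was seen; as first matched it had 15 higher and 6 lower of 107 and was not called (shift 0.31, adjusted p = 0.18).

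**Figure D3:**
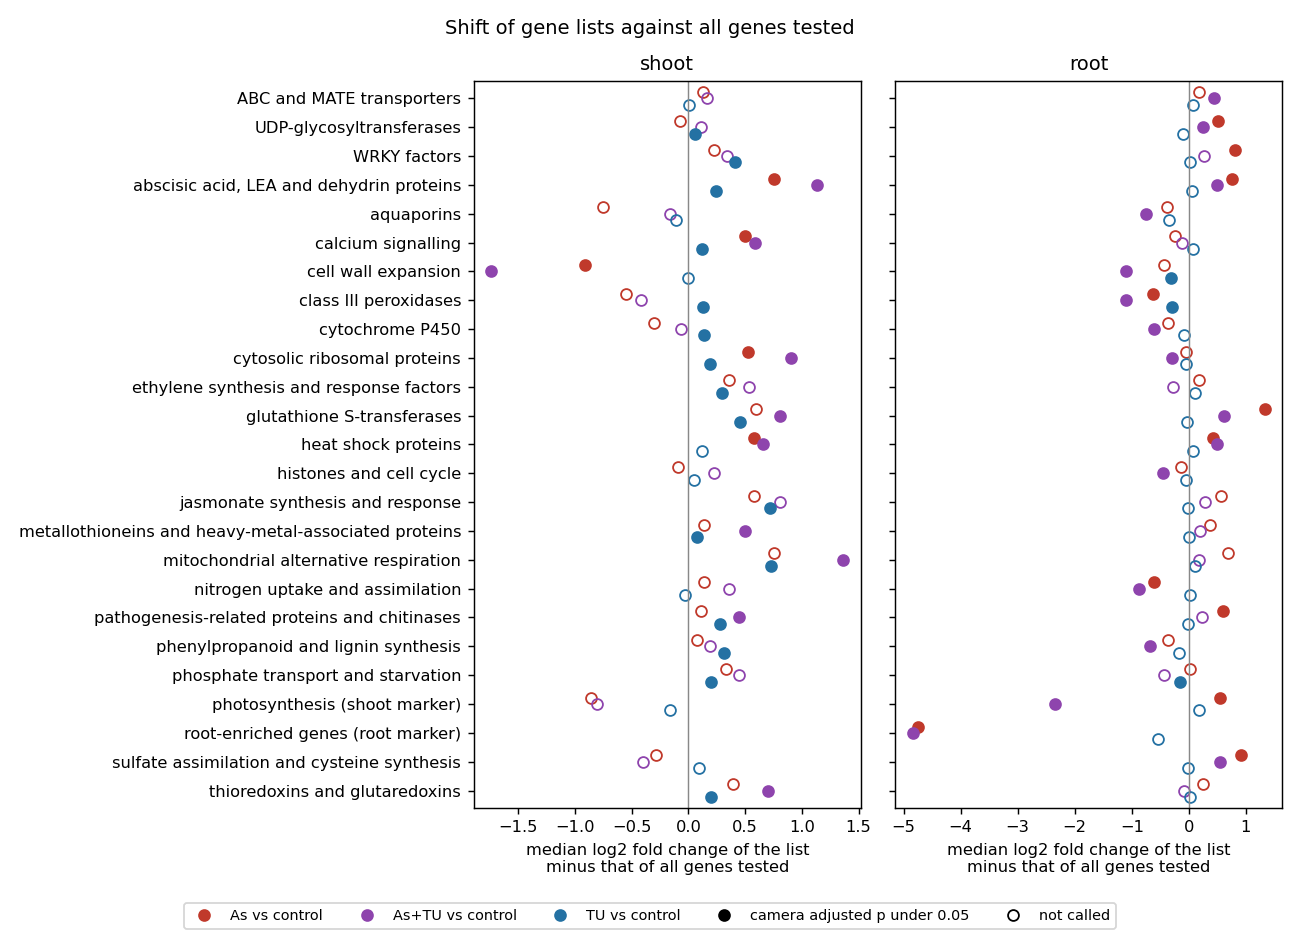
Median log2 fold change of 25 gene lists minus that of all genes tested, in shoots and roots, for As, As+TU and TU against control, with filled symbols where camera's adjusted p was under 0.05. The ABC and MATE list is drawn as corrected after its test had been seen and was not called as first matched (adjusted p = 0.18 for As+TU in roots); abscisic acid, LEA and dehydrin genes lie at 0.76 for As and 1.13 for As+TU in shoots.

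The arsenic changes with and without thiourea against the shared controls correlated across genes at r = 0.874 in shoots and 0.852 in roots, where simulated unchanged groups gave 0.499 in both, and genes are not independent replicates. The covariances were 1.74 and 1.82, and the simulated ones 0.175 and 0.166. In shoots 1346 genes were higher in both and 1574 lower in both, against 147 and 412 for independent lists, with 3 in opposite directions. In roots 1584 were higher and 975 lower in both, against 177 and 107, with 1 in opposite directions. The simulated groups shared 0 called genes in either direction. With control array 1 for As and control array 2 for As+TU, so that no array was shared, r was 0.759 in shoots and 0.582 in roots. In shoots 555 genes were then higher and 500 lower in both, against 31.7 and 60.9, with 3 in opposite directions. In roots 908 were higher and 350 lower, against 92.7 and 36.2, with 5 in opposite directions. With the control arrays the other way round, r was 0.806 and 0.802. In shoots 557 were higher and 478 lower in both, against 25.2 and 32.6, and in roots 1004 and 347, against 71.3 and 17.

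Arsenic was also compared on the thiourea background, As+TU against TU, which shares no array with the comparison of arsenic alone. In shoots abscisic acid, LEA and dehydrin genes shifted up by 0.82 (also with scan session as a block), with 24 higher and 2 lower of 79, or 27 and 3 over the list alone (adjusted p = 5.71e-10, and 0.129 with an estimated correlation). Heat shock genes shifted up by 0.53 (block 0.52), with 18 higher and 2 lower, or 18 and 3 over the list alone (adjusted p = 1.82e-04, and 0.0985 with an estimated correlation). Cell wall expansion genes shifted by -1.60 (-0.93 with the block and without As+TU array 1), with 3 higher and 24 lower, or 5 and 26 over the list alone (adjusted p = 0.00321, and 0.528 with an estimated correlation). The count was 4366, 1677 higher and 2689 lower, or 2003 with the block and 2018 without the later-scanned arrays. The higher share was 38.4%, or 48.1% with quantile normalization. Leaving out As+TU array 1 gave 2475, TU array 1 1174 and TU array 2 2455.

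In roots the same comparison gave the 5 root-enriched genes 0 higher and 4 lower, also over the list alone. Their shift was -4.11 over the 4 genes tested and -4.35 over all 5 (block -4.14, earlier-scanned arrays -3.69 over the 4; adjusted p = 6.66e-04, and 0.177 with an estimated correlation). Photosynthesis genes shifted by -2.48 (block -3.15, earlier-scanned arrays -2.91), with 1 higher and 6 lower of 51, or 1 and 9 over the list alone (adjusted p = 4.48e-06, and 0.529 with an estimated correlation).

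As+TU against TU in roots also gave glutathione S-transferase genes 0.75 above the median of all genes (block 0.81, earlier-scanned arrays 1.06), with 22 higher and 3 lower of 61, or 24 and 8 over the list alone (adjusted p = 6.66e-04, and 0.402 with an estimated correlation). Their shift was 0.354 without As+TU array 1, 1.21 without As+TU array 2 and 0.481 without TU array 1. Abscisic acid, LEA and dehydrin genes shifted up by 0.47 (block 0.539, earlier-scanned arrays 0.496), with 24 higher and 6 lower of 82, or 27 and 8 over the list alone (adjusted p = 6.66e-04, and 0.229 with an estimated correlation). Sulfate assimilation genes shifted up by 0.84 (block 0.88, earlier-scanned arrays 1.03), with 7 higher and 1 lower of 23, or 9 and 4 over the list alone (adjusted p = 0.0126, and 0.218 with an estimated correlation). Heat shock genes shifted up by 0.44 (block 0.44, earlier-scanned arrays 0.45), with 24 higher and 4 lower, or 33 and 5 over the list alone (adjusted p = 2.6e-05, and 0.0616 with an estimated correlation). Auxin response genes shifted by -0.50, with 4 higher and 10 lower of 84, also over the list alone (adjusted p = 0.021, and 0.218 with an estimated correlation). The shift was -0.47 with the block and not called in the earlier-scanned arrays (-0.38, adjusted p = 0.0607), without As+TU array 2 (-0.359, adjusted p = 0.0552) or without TU array 2 (-0.376, adjusted p = 0.0561). The count was 2897, 1722 higher and 1175 lower, or 1870 with the block and 1486 without the later-scanned arrays. Leaving out As+TU array 1 gave 1676, As+TU array 2 1789, TU array 1 1812 and TU array 2 1412.

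The arsenic changes without and with thiourea, from separate arrays, correlated across genes at r = 0.85 in shoots and 0.842 in roots, with simulated values of 0.0016 and 0.00487. The covariances were 1.49 and 1.71, against simulated values of 5.58e-04 and 0.00161. In shoots 1112 genes were higher in both and 1252 lower in both, where independent lists would share 89.2 and 174, and 2 went in opposite directions. In roots 1479 were higher and 822 lower in both, against 161 and 82.8, and 2 went in opposite directions.

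Thiourea alone was compared with control to find what it does without arsenic. Scan session as a block could not move the list shifts in shoots, since the shoot control and TU arrays were all read in the earlier session. In shoots jasmonate synthesis and response genes shifted up by 0.72 relative to all genes (adjusted p = 3.16e-11, and 0.349 with an estimated correlation), with 0 of 36 called, or 0 over the list alone. Without TU array 2 the shift was 0.329. The 12-oxophytodienoic acid reductase genes Os06g0216300 and Os06g0215900 had values of 2.47 ± 0.68 (adjusted p = 0.836) and 2.98 ± 0.83 (adjusted p = 0.837). Glutathione S-transferase genes shifted up by 0.46, with 0 of 50 called, or 0 over the list alone (adjusted p = 1.63e-06, and 0.418 with an estimated correlation). WRKY factor genes, which act in defence, shifted up by 0.41, with 0 of 61 called, or 0 over the list alone (adjusted p = 2.1e-04, and 0.418 with an estimated correlation). They were not called without control array 1 (0.0473, adjusted p = 0.107) or TU array 2 (0.156, adjusted p = 0.0766). In these shoots Lsi1 (Os02g0745100) had a value of -0.92 ± 0.42 (adjusted p = 1) and the metallothionein Os12g0571000 1.24 ± 0.62 (adjusted p = 1).

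Thiourea called 2 of 26717 shoot genes, against 845 at an unadjusted p under 0.05 and 2 calls both with scan session as a block and without the later-scanned arrays. They were a gene for a nucleotide-binding leucine-rich-repeat protein (Os11g0243400), at least 5.47-fold higher (adjusted p = 0.00987), and Os01g0362800, with no description, named after its values were seen and at least 6.45-fold higher (adjusted p = 0.0144). Leaving out control array 1 ended both calls (adjusted p = 0.131 for each), and for Os01g0362800 so did leaving out control array 2 (0.0593) or TU array 1 (0.0523). Both calls also ended with normexp background correction (adjusted p = 0.868 for each, with log2 changes of 1.06 and 1.27) and with only the shoot arrays in the fit (adjusted p = 0.624 for each). The count was 0 without control array 1, 1 without control array 2, 12 without TU array 1, and 10 without TU array 2, As+TU array 1 or As+TU array 2. Quantile normalization and array weights each raised the count. The median of all genes was -0.16, or -0.12 with quantile normalization.

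In thiourea-treated roots, cell wall expansion genes shifted by -0.32, or -0.51 in the earlier-scanned arrays, with 0 of 74 called, or 0 over the list alone (adjusted p = 1.76e-05, and 0.831 with an estimated correlation). Class III peroxidase genes shifted by -0.30, or -0.40 in the earlier-scanned arrays, with 0 of 105 called, or 0 over the list alone (adjusted p = 2.9e-04, and 0.831 with an estimated correlation). Scan session as a block could not move either shift, since control and TU each had an array in the later session. Neither list was called without control array 1 (-0.557, adjusted p = 0.0556, and -0.334, adjusted p = 0.0637) or TU array 1 (-0.246, adjusted p = 0.0984, and -0.163, adjusted p = 0.312). Lsi1 (Os02g0745100) had a value of -0.38 ± 0.42 and APS reductase (Os07g0509800) -0.07 ± 0.34, both with adjusted p = 1. The 2 genes called of 25634 were Os02g0662300, at least 11.9-fold higher (adjusted p = 0.0163), and Os01g0886350, at least 9.94-fold higher (adjusted p = 0.0355), neither with a description and both named after their values were seen. An unadjusted p under 0.05 was reached by 421 genes.

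The thiourea count in roots was 9 with scan session as a block and 1 without the later-scanned arrays, and 1 gene was called within each session. Both root calls ended with normexp background correction (adjusted p = 0.212 for Os02g0662300 and 0.848 for Os01g0886350), with only the root arrays in the fit (0.0519 and 0.124), with a replicate block (0.0723 and 0.0728) and without the later-scanned arrays (0.172 and 0.0678). That of Os01g0886350 also ended with array weights (0.0788), no filter (0.0646), every probe tested separately (0.055) and an intensity trend (0.0525). The changes of the 2 sessions correlated across genes at r = -0.325. The count was 0 without control array 1, control array 2, shoot arsenic array 1 or shoot arsenic array 2, and 12 without TU array 1. It was 8 without As+TU array 1 or 2, 6 without shoot As+TU array 1 or 2, 4 without shoot TU array 1 or 2, and 1 without arsenic array 1 or 2. The call of Os02g0662300 ended without control array 1 (adjusted p = 0.121), control array 2 (0.0602) or shoot arsenic array 1 or 2 (0.0535 each). The call of Os01g0886350 ended without control array 1 (adjusted p = 0.217), control array 2 (0.143), shoot arsenic array 1 or 2 (0.0603 each) or root arsenic array 1 or 2 (0.0535 each).

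Whether thiourea changed arsenic-treated seedlings was tested directly as As+TU against As. In shoots glutathione S-transferase genes shifted up by 0.48 (0.69 with scan session as a block), with 0 of 50 called, or 0 over the list alone (adjusted p = 1.97e-04, and 0.407 with an estimated correlation). They were not called without As+TU array 2 (0.143, adjusted p = 0.152). Pathogenesis-related and chitinase genes shifted up by 0.31 (0.60 with the block), with 0 of 80 called, or 0 over the list alone (adjusted p = 0.00196, and 0.407 with an estimated correlation). Without As+TU array 1 the shift was 0.603, and without As+TU array 2 it was -0.0257 and not called (adjusted p = 0.714). The type 1 metallothionein Os12g0571000 had a value of -0.07 ± 0.62, OsEXPA2 (Os01g0823100) 0.56 ± 0.43 and the LEA-like gene Os05g0542500 0.23 ± 0.43, with adjusted p-values of 0.994, 0.804 and 0.949. The 7 genes called of 26717, all higher in As+TU, were named after their values were seen: Os05g0456950 (similar to an RCC1 family protein), Os06g0140200 (a leucine-rich repeat protein), Os01g0327500, Os03g0379000, Os11g0618500, Os06g0149000 and Os06g0588800. Their bounds ran from at least 3.23-fold to at least 13.4-fold, with adjusted p from 0.0285 to 0.038, and Os05g0456950, Os06g0140200 and Os11g0618500 had a usable spot on 1 As+TU array. All 7 calls ended without arsenic array 1, where 9 other genes were called, 0 higher and 9 lower (adjusted p for the 7 from 0.0737 to 0.112). All 7 also ended without arsenic array 2 and without root As+TU array 1 or 2. They ended as well with normexp, with only the shoot arrays, with array weights, with an intensity trend and with a replicate block. The strict filter called 0 genes.

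An unadjusted p under 0.05 was reached by 2118 shoot genes in that comparison. The count was 16 with scan session as a block and 13 without the later-scanned arrays. These counts leave out some of the 7: the call of Os03g0379000 ended with the block (adjusted p = 0.101) and without the later-scanned arrays (0.124), which also ended those of Os06g0140200 (0.0575) and Os06g0588800 (0.0517). The last 2 ended with no filter (0.0579 and 0.0679), with every probe tested separately (0.0539 and 0.0554) and without either array of root control (0.0541), root arsenic (0.0528) or root TU (0.0503). So did Os06g0140200 without either shoot control array (0.0623), Os06g0588800 without either shoot TU array (0.0546) and Os03g0379000 without As+TU array 1 (0.0584). The count was 9 (0 higher, 9 lower) without arsenic array 1, 0 without arsenic array 2, root As+TU array 1 or root As+TU array 2, 22 without As+TU array 1 and 939 (50 higher, 889 lower) without As+TU array 2. The median of all genes was -0.14.

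In roots photosynthesis genes shifted by -3.04 in As+TU against As, with 0 of 51 called, or 0 higher and 30 lower over the list alone (adjusted p = 1.25e-22, and 0.644 with an estimated correlation). Most of this shift came from arsenic array 2, where the median signal of 59 photosynthesis genes was 2.89, against -1.21 on arsenic array 1 and -1.85 and -1.77 on the As+TU arrays. Without arsenic array 2 the shift was -0.709 (adjusted p = 7.51e-05), and without arsenic array 1 -5.39. Cell wall expansion genes shifted by -0.51, with 0 of 74 called, or 0 over the list alone (adjusted p = 1.86e-04, and 0.644 with an estimated correlation). The shift was -0.853 without As+TU array 1 and not called without As+TU array 2 (-0.236, adjusted p = 0.0553). Cytosolic ribosomal protein genes shifted by -0.16, with 0 of 139 called, or 0 over the list alone (adjusted p = 0.00659, and 0.644 with an estimated correlation), but by 0.16 with quantile normalization (adjusted p = 0.0426). They were not called without arsenic array 1 (-0.117, adjusted p = 0.0604) or As+TU array 2 (-0.109, adjusted p = 0.131). Lsi1 (Os02g0745100) had a value of -0.08 ± 0.42 (adjusted p = 0.963), APS reductase (Os07g0509800) 0.44 ± 0.34 (adjusted p = 0.646) and Oshsp18.0 (Os03g0267000) -0.80 ± 0.37 (adjusted p = 0.479). The 4 genes called, none with a description and all named after their values were seen, were Os06g0703300 (at least 6.44-fold higher, adjusted p = 0.0151), Os05g0575500 (3.11 ± 0.34, adjusted p = 0.0151), Os08g0322500 (at least 6.36-fold higher, adjusted p = 0.0479) and Os02g0653300 (at least 6.11-fold lower, adjusted p = 0.0151).

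These 4 root calls stood against 2673 genes at an unadjusted p under 0.05, and the count was 5 with scan session as a block and 2 without the later-scanned arrays. The call of Os08g0322500 ended with that block (adjusted p = 0.0931). Without the later-scanned arrays it ended too (0.135), as did those of Os06g0703300 and Os05g0575500 (0.0796 each), which a replicate block also ended (0.0832 each). No filter ended the calls of Os05g0575500 (0.0501) and Os08g0322500 (0.0885), and array weights (0.0748), every probe tested separately (0.0587) and the median scaling (0.0518) that of Os08g0322500. All 4 calls ended with normexp background correction (adjusted p from 0.212 to 0.377) and with only the root arrays in the fit (0.0767 to 0.148). With quantile normalization 40 genes were called, 16 higher and 24 lower. The count was 216 (7 higher, 209 lower) without arsenic array 1, 0 without arsenic array 2 or As+TU array 2, and 14 without As+TU array 1. Without arsenic array 2 the adjusted p was 0.0914 for Os06g0703300, 0.0725 for Os05g0575500, 0.0975 for Os02g0653300 and 0.138 for Os08g0322500, and without As+TU array 2 it was 0.0853, 0.0731, 0.0573 and 0.143. Without As+TU array 1 it was 0.0534 for Os06g0703300 and 0.0603 for Os05g0575500. The call of Os08g0322500 also ended without either array of root control (0.0799), root TU (0.0971), shoot control (0.0772), shoot arsenic (0.0525) or shoot As+TU (0.0648).

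The interaction term asked whether the arsenic change itself differed with thiourea. In shoots OsEXPA2 (Os01g0823100) had an interaction of 0.70 ± 0.61, the metallothionein Os12g0571000 -1.31 ± 0.88 and Os05g0542500 0.13 ± 0.61, each with adjusted p = 1. Jasmonate genes had an interaction of -0.43, with 0 of 36 called, or 0 over the list alone (adjusted p = 9.03e-04, and 0.879 with an estimated correlation), which was -0.19 and not called with scan session as a block (adjusted p = 0.305) or without As+TU array 1 (adjusted p = 0.27), and -0.258 and not called without TU array 2 (adjusted p = 0.251). It was -0.156 without arsenic array 2 and -0.886 without As+TU array 2. In roots Lsi1 (Os02g0745100) had an interaction of 0.30 ± 0.59, APS reductase (Os07g0509800) 0.51 ± 0.48 and Oshsp18.0 (Os03g0267000) -0.58 ± 0.53, each with adjusted p = 1. Photosynthesis genes had an interaction of -3.13 in roots, and -2.97 in the earlier-scanned arrays, with 0 of 51 called, or 0 over the list alone (adjusted p = 2.57e-30, and 0.483 with an estimated correlation). Most of it came from root arsenic array 2. Without that array the interaction was -0.985 (adjusted p = 6.23e-08), and without arsenic array 1 -5.45.

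Limma called 0 genes for the interaction in shoots (smallest adjusted p = 0.0731; 497 at an unadjusted p under 0.05) and 0 in roots (smallest adjusted p = 0.29; 637). With scan session as a block it called 5 and 1, and without the later-scanned arrays 1 and 1. In shoots the count was 6 without As+TU array 1 and 2 without As+TU array 2 or TU array 2. In roots it was 109 (1 higher, 108 lower) without arsenic array 1, and 1 without shoot control array 1, shoot control array 2 or TU array 2. On simulated data, 0% of 8-fold interactions were called in shoots and 7.58% in roots, so most interactions of that size went uncalled in both organs.

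The other organ differences tested were those of the thiourea change and of As+TU against As. For thiourea, scan session as a block could not move the list shifts of this difference. Jasmonate genes differed by -0.58 between roots and shoots, and by -1.19 in the earlier-scanned arrays, with 0 of 33 called, or 0 over the list alone (adjusted p = 4.68e-08, and 0.352 with an estimated correlation). Leaving out 1 array moved it to -0.911 (shoot TU array 1), -0.299 (shoot TU array 2), -0.902 (root control array 1), -0.371 (root control array 2), -0.377 (root TU array 1) and -0.996 (root TU array 2). Phenylpropanoid and lignin genes differed by -0.39, and by -0.72 in the earlier-scanned arrays, with 0 of 52 called, or 0 over the list alone (adjusted p = 2.1e-05, and 0.352 with an estimated correlation). The shift was -0.254 without shoot TU array 2 and -0.252 without root TU array 1. Allene oxide synthase (Os02g0218700), an early enzyme of jasmonate synthesis, was above background on 0 of 2 shoot TU arrays, so the size of its difference is not measured (adjusted p = 1). For this difference 289 genes had an unadjusted p under 0.05, a smaller share than the 0.05 expected without any change. Limma called 0 genes, and 0 with the block.

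For As+TU against As, photosynthesis genes differed by -2.94 between roots and shoots, or -3.16 with scan session as a block, with 0 of 51 called, or 0 over the list alone (adjusted p = 2.28e-15, and 0.376 with an estimated correlation). Most of this difference came from root arsenic array 2. Without it the difference was -0.76 (adjusted p = 6.76e-04), and without root arsenic array 1 -5.28. Glutathione S-transferase genes differed by -0.88 (-1.12 with the block), with 0 of 48 called, or 0 over the list alone (adjusted p = 1.65e-05, and 0.376 with an estimated correlation). The shift was -0.558 without shoot As+TU array 2 and -0.555 without root As+TU array 2. Oshsp18.0 (Os03g0267000) had a difference of -0.33 ± 0.53 (adjusted p = 0.774) and the peroxidase Os05g0135500 0.74 ± 0.39 (adjusted p = 0.543). Limma called 0 genes (2011 at an unadjusted p under 0.05), and 1 both with the block and without the later-scanned arrays. The count was 91 without root arsenic array 1, and 1 without shoot As+TU array 1 or 2.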

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

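The tests of scan session, scaling and background on the number of genes called in shoots were chosen after the counts had been seen; the tests on photosynthesis transcripts in roots were written before their results.

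The arsenic response differed between roots and shoots in 1730 genes by a test of the difference itself. The naming rule gave the 3 largest fitted differences in each direction among described genes, as root change minus shoot change on the log2 scale. They were 16.05 for the alpha-amylase 3D gene Os08g0473900, 12.81 for the glycine-rich RNA-binding protein gene Os05g0223200 and 10.24 for the B12D gene Os07g0604600. On the other side they were -9.39 for the dehydrin RAB 16D (Os11g0453900), -8.14 for the urea transporter-like gene Os10g0580400 and -7.50 for the aldehyde oxidase Os07g0281800. The size is not measured for Os08g0473900, Os05g0223200 and Os07g0604600, above background on 0 of 2 root control arrays, nor for Os11g0453900, above background on 0 of 2 shoot control arrays. Each organ had its own slide, but control and As arrays of an organ shared a slide and row, so an additive slide effect cancels in the difference. Os10g0580400 fell from 2.38 to -3.09 between the control and As means in roots and rose from -1.71 to 0.956 in shoots. No explanation of the difference was tested.

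More shoot genes were called for arsenic with thiourea (9142) than for arsenic alone (3145), although As+TU against As called 7. Scan session does not account for the whole difference: without the later-scanned As+TU array 4105 were called, where leaving out 1 arsenic array left 1568 or 1670 for arsenic alone. Whether it accounts for part is open, since the block leaves 1 As+TU array in effect. The counts also argue against scaling and genes near background as the whole cause, with 8511 against 3724 calls under quantile normalization and 5247 against 2408 among genes above background on all shoot arrays. The slide row, the spread of the As+TU arrays and an effect of thiourea stay open.

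Photosynthesis transcripts differed between root arrays, with a median log2 signal over 59 genes of 2.89 on arsenic array 2 and -1.21 on arsenic array 1. Scaling is argued against, since over the 51 of these genes tested in roots the medians were 3.27 and -1.03, and 3.10 and -0.944 with quantile normalization, still a gap of 4.04. Shoot tissue carried into that root sample is a candidate explanation. The excess of array 2 over array 1 was 9.31% of the level in arsenic-treated shoots among 42 photosynthesis genes and 7.63% among 246 other shoot-enriched genes, a ratio of 0.82 (95% interval 0.683 to 1.01). A greening of those roots stays open for chloroplast genes, though the share was 7.61% among 225 shoot-enriched genes without a chloroplast description and 7.99% among 21 with one.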

How the results depend on the processing

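The fits without the later-scanned arrays, the lists under other scalings, background correction, scan session or fewer arrays, and the transporter list as first matched were chosen after the data had been seen.

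With 2 arrays per group, counts moved by more than 1.5 times under many alternatives; except where the alternative itself tests fewer genes or arrays, or more probes, the cause was not tested. Signal near background left 584 of 3145 calls for As in shoots, 2720 of 9142 for As+TU in shoots, 847 of 4210 for As in roots and 760 of 3414 for As+TU in roots with only a bound on their size. The value table, the median scaling and a 2-fold minimum moved no count by that much.

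Every probe tested separately gave 5197 calls for As in shoots, 6572 for As in roots, 5470 for As+TU in roots, 4573 for As+TU against TU in roots, 2812 for the organ difference of As and 1 for TU in roots. Array weights gave 5096 for As, 30 for TU, 0 for As+TU against As and 2773 for As+TU against TU in shoots, and 1 for TU in roots. Quantile normalization gave 36 for TU, 61 for As+TU against As and 30 for the interaction in shoots, and 8, 40 and 12 in roots. Normexp background correction gave 0 for TU and for As+TU against As in both organs, and 3058 for the organ difference of As. The strict filter gave 0 for TU, 5247 for As+TU, 0 for As+TU against As and 2642 for As+TU against TU in shoots, and 0 for TU and 1 for As+TU against As in roots. No filter gave 2629 for As+TU against TU in shoots, and 1 for TU and 2 for As+TU against As in roots; the correlation of the arsenic effects without and with thiourea became 0.711 in shoots and 0.729 in roots. The tissue's own arrays alone gave 0 for TU, 0 for As+TU against As and 2893 for As+TU against TU in shoots, and 0 for As+TU against As in roots. An intensity trend with robust variance gave 0 for As+TU against As in shoots, and 1 for TU and 8 for As+TU against As in roots.

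Replicate numbers do not pair all groups: array 1 minus array 2 correlated at 0.413 to 0.53 among shoot control, As and As+TU. With shoot TU it was -0.459 to -0.113, and in roots -0.577 to 0.459. A replicate block gave 5 calls for TU and 0 for As+TU against As in shoots, and 1 and 2 in roots.

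With scan session as a block the counts in shoots were 3487 for As+TU, 16 for As+TU against As, 2003 for As+TU against TU and 5 for the interaction. In roots they were 2693 for As, 9 for TU, 2218 for As+TU, 1870 for As+TU against TU and 1 for the interaction, and for the organ differences 935 for As and 1 for As+TU against As. Without the later-scanned arrays they were 3766, 13, 2018 and 1 in shoots, in that order. In roots they were 2234 for As, 1 for TU, 2242 for As+TU, 2 for As+TU against As, 1486 for As+TU against TU and 1 for the interaction, and for the organ differences 741 for As, 1 for TU and 1 for As+TU against As.

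Leaving out 1 array gave 1250 to 3326 calls for As, 0 to 12 for TU, 2133 to 9379 for As+TU, 0 to 939 for As+TU against As, 1174 to 5002 for As+TU against TU and 0 to 6 for the interaction in shoots. In roots the ranges were 2156 to 4503, 0 to 12, 1829 to 3651, 0 to 216, 1412 to 3095 and 0 to 109. The organ differences ranged from 712 to 1854 for As, 0 to 1 for TU and 0 to 91 for As+TU against As. The correlation of the arsenic effects ranged from 0.761 to 0.859 in shoots and from 0.751 to 0.854 in roots.

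Of 354 called results of single genes, 320 stayed called with scan session as a block, 299 without the later-scanned arrays, 312 with normexp, 346 with quantile normalization and 329 with no filter. The strict filter left 202 to test, all called, and the tissue's own arrays kept 281 and lost 29. Leaving out 1 array kept 5335 calls and lost 323. The organ difference of Os04g0445100 for As was 0.000945 with normexp (adjusted p = 0.999), with the sign opposite to its value of -3.49. Of 158 called lists, fry kept 48, quantile normalization 134, normexp 146 and the block 149. Where the block cannot move a shift by design, a call kept with it is no check. The earlier-scanned arrays kept 135 and turned 1, ribosomal proteins in the organ difference of TU (0.14, adjusted p = 0.264, from -0.19). Cytosolic ribosomal protein genes in As+TU against As in roots turned from -0.163 to 0.157 with quantile normalization (adjusted p = 0.0426). Leaving out 1 array at a time kept 2295 of 2528 list calls, and 62 lists stayed called each time. The median shift changed sign in 13, of which 1 was called. In 3 of these camera's direction turned as well. Photosynthesis genes ranged from -1.4 to 2.84 for As in roots and from -0.421 to 3.68 for its organ difference, with both lowest values without root As array 2 (adjusted p = 0.00114 and 0.645). Cytochrome P450 genes in the organ difference of TU ranged from -0.382 to 0.0669, the highest without root control array 2 (adjusted p = 0.905).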

Other observations

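The low-oxygen list and its tests were chosen after gene values in roots had been seen and before the list itself was tested; the tests of the interaction over responding genes were written before their results.

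Genes of the low-oxygen response were among the large changes in arsenic-treated roots. Non-symbiotic hemoglobin 2 (Os03g0226200), which binds oxygen and nitric oxide, rose by 6.32 ± 0.65 (adjusted p = 9.04e-05, n = 2), while hemoglobin 4 (Os03g0234100) was at least 16.5-fold lower (adjusted p = 8.32e-04). A B12D family gene (Os07g0604700) was at least 9.61-fold higher (adjusted p = 4.73e-04). Lactate dehydrogenase B (Os06g0104900), an enzyme of fermentation, rose by 3.68 ± 0.61 and alcohol dehydrogenase 1 (Os11g0210300) by 1.43 ± 0.30. Sucrose synthase 1 (Os03g0401300) changed by -2.66 ± 0.54 (adjusted p = 0.00627), and was not called without root control array 1 (-2.47, adjusted p = 0.0503) or without the later-scanned arrays (-2.47, adjusted p = 0.0705). Of 30 measured genes on the list 9 were higher and 4 lower in roots, and of 27 in shoots 8 were higher and 3 lower. These genes were named after their values were seen.

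The hypothesis that arsenic raises low-oxygen genes in roots as a group may hold or not: their shift relative to all genes was 0.24 (camera p = 0.135, and p = 0.258 with an estimated correlation). In shoots the shift was 0.61 (p = 0.0146, and 0.0763 with an estimated correlation). With thiourea added, the shift against control was -0.05 in roots (8 higher, 5 lower; p = 0.481 with an estimated correlation) and 0.37 in shoots (10 higher, 3 lower; p = 0.00466, and 0.0461 with an estimated correlation). The difference between organs for arsenic alone was -0.18 (p = 0.605 with an estimated correlation). The fry test, which sets the list against no change rather than against the other genes, pointed up for arsenic in roots (signed fry test by rotations, not an exact test, p = 0.00968) and in shoots (p = 0.00127), also with thiourea added (p = 0.0334 and 5.38e-04), and down in the difference between organs (p = 0.202). It favours a rise in both organs, without testing whether it exceeds that of other genes. The predictions had taken any p at or above 0.05 as excluding the hypothesis; that bound was wrong, because a p that misses the threshold does not exclude an effect, and the reading was changed to undecided after the values were seen.

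Thiourea may weaken the arsenic effect across responding genes. In roots 66.6% of 6963 genes that responded to arsenic on average over both backgrounds had an interaction opposite to their response, with a median of -0.25 in the direction of the response (signed fry test by rotations, p = 0.148; no exact test was possible with 2 arrays per group). In shoots 40.4% of 10164 did, with a median of 0.12 (p = 0.612 by the same test, not an exact one). The same change of reading as above applies to both tests. The predictions had also taken an interaction with the sign of the response, or a low-oxygen difference at or below 0, as excluding. The shoot median of 0.12 and the organ difference of -0.18 lie on that side, but not by more than their spread in the tests given above, so neither decides.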
